A study of Mus musculus with 44 samples.

How the data were processed

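RNA of fetal placenta and maternal decidua of Swiss Webster mice was measured on Affymetrix whole-genome mouse arrays. Per the labels' protocols, decidua was separated from placenta with forceps, tissue was pooled by litter with 2 to 10 placentas in a sample and 2 of the earliest samples pooled over litters, and 10 ug of RNA was labelled with biotin. Per the same protocols, the first and second e8.5 placental samples were taken up in another lysis buffer and extracted with a micro-scale kit, and the other samples were extracted with Trizol and a column kit. The deposited values are intensity, 1 per probe set and array. The method by which the authors summarized and normalized the probe sets is not given in the sources used here. The deposited values were positive and linear, and their quantiles differed between arrays. The probe set values as deposited were thus not equal in quantiles, and whether an earlier step used quantile normalization is not known. The number of arrays limits the precision.

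The data held 45101 probe sets, of which 64 control probe sets were left out. GEO's platform annotation gave 34945 probe sets exactly 1 gene and 932 several, and did not list 9160. Of those with 1 gene, 34741 were found by Entrez ID in a RefSeq gene table of the assembly GRCm38.p6, used for names only, and 0 symbols needed an update. A gene was represented by the probe set with the highest mean over all arrays among those with exactly 1 gene, which gave 18193 genes, 9010 of them with more than 1 probe set. Prl3d1, Prl3b1, Prl2c2, Gcm1, Syna, Synb, H19 and Ddx3y were not analysed here. The main comparisons called opposite directions for probe sets of Hbb-b2, and another probe set opposed the named one for Rxra in decidua and Cts8 between tissues.

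Values were turned into log2(intensity + 16) here, with no other scaling and no filter on dim genes. The e8.5 samples with 2 technical arrays were averaged first and counted as 1 replicate each. A linear model with 1 mean for each of the 17 groups was fitted over all 40 biological replicates with limma 3.58.1 (lmFit, contrasts.fit, eBayes) in R 4.3.3, version 1.17.8 of the package data.table read the data, and figures were drawn with matplotlib 3.10.9 in Python 3.11.15. Contrasts were late (mean of e15.0, e17.0, e19.0 and P0) minus early (mean of e8.5, e9.0 and e10.5) in placenta and in decidua, the difference of these, placenta minus decidua over the 8 shared stages, and each step between neighbouring stages. A gene was called at a Benjamini-Hochberg adjusted p under 0.05 and an absolute log2 difference of at least 1. The samples were not treated as paired. Leaving out a replicate of a group of 2 leaves a lone sample, which is then assumed to vary like the other groups.

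Gene lists were written before the data were examined, as were the contrasts, most of the alternatives and the rule for named genes. They covered the prolactin family, placental cathepsins, pregnancy-specific glycoproteins, giant cell, spongiotrophoblast and glycogen cell, labyrinth and syncytiotrophoblast, and stem and progenitor genes, nutrient transporters and imprinted genes. They also covered decidual stromal, uterine natural killer, macrophage, neutrophil, embryonic haemoglobin, definitive erythroid, yolk sac endoderm, endothelial, smooth muscle and uterine epithelial genes. The rest were matrix, cell cycle, hypoxia, steroid, complement and coagulation, interferon, immediate early and heat shock, oxidative phosphorylation, ribosomal protein and Y-linked genes. Some genes stand on more than 1 list, such as Eomes (stem and natural killer), Prl8a6 and Prl8a8 (prolactin and spongiotrophoblast), Adm (giant cell and hypoxia), Cubn (transporter and yolk sac), Sox17 (yolk sac and endothelial) and C1qa (macrophage and complement). Lists were tested with camera at a preset correlation of 0.01, adjusted over the lists of a contrast, and again with an estimated correlation and with fry.

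Named genes were the 10 largest called rises and falls per main comparison that also held in every replicate or stage, and the 5 largest each way for the difference between tissues, for the step of each tissue with most calls and for e19.0 to P0. To these came up to 4 called members and the largest uncalled member of each list, fixed landmark genes and the Y-linked genes. Genes whose highest stage mean lay under the median of all genes (8.22) were not named by size. The plots show lists and genes chosen after their values were seen.

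The fit was tested on simulated data for 18193 genes with 200 changed, 100 by 1.5 and 100 by 3 on the log2 scale. The noise was normal and independent between genes and samples, with 1 SD per gene for every sample. The real samples spread unevenly (array weights from 0.30 to 8.81), so the counts below hold for even and independent noise only. All 100 changes of 3 were recovered in each comparison simulated. Of the changes of 1.5, the fit recovered 98 of 100 for placenta late against early, 100 for decidua, 100 between tissues and 97 for the difference between tissues. For steps it recovered 97 of 100 in placenta from e10.5 to e12.0, 95 in placenta from e19.0 to P0, 90 in decidua from e8.5 to e9.0 and 91 in decidua from e19.0 to P0. Unchanged genes called numbered 0, 1, 0, 0, 1, 1, 2 and 5 in the same order.

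Alternatives were quantile normalization, scaling to the 75th percentile, pseudocounts of 1 and 64, dim genes left out, the mean or each of a gene's probe sets, array weights, a mean-variance trend, a fit on 1 tissue, every array with a random block, and the first technical array alone. Further ones were a replicate block, leaving out each replicate, the other lysis buffer, e8.5 or P0, and a linear trend over stages. Added after the data were seen were the first e9.0 placental sample left out and the first 2 e8.5 replicates of a tissue counted as 1 sample, and list counts under these settings. For placental transcripts in late decidua, the rise over early decidua was computed as a percent of late placenta minus early decidua, on the linear scale, for genes at least 4 times brighter in late placenta than in early decidua with a late placental intensity over 500. Added after the data were seen were the plain percent of late decidua over late placenta, the same rise less the median of the 40 genes closest in late placental brightness, the level of the genes over 8000 in late placenta, with limits of 1, 0.5 and 0.25 times the median of the 2 lists, and the Y-linked probe sets called between tissues. Decidual genes in placental samples were given as the plain percent of the decidual intensity of the same stage, for genes with a decidual intensity over 1000.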

Results

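Fetal placenta and maternal decidua of Swiss Webster mice were profiled separately on whole-genome expression arrays, from e8.5 of gestation to the day of birth (P0). The 44 arrays came from 40 biological replicates in 17 groups, with 24 replicates of placenta at 9 stages and 16 of decidua at 8 stages. Placenta had 3 replicates at e8.5, e9.0, e10.5, e12.0, e15.0 and e17.0, and 2 at e13.5, e19.0 and P0. Decidua had 2 replicates at each of its 8 stages and was not sampled at e13.5. The 75th percentile of an array lay between 383 and 471, and the highest value between 18066 and 33282. The number of arrays limits the precision of every value below. Differences are on the scale of log2(intensity + 16), which understates the change of dim genes, and each is given ± its standard error from the limma fit. A gene was counted as changed at a Benjamini-Hochberg adjusted p under 0.05 with a log2 difference of at least 1 in either direction, among 18193 genes. The limma p-values measure the spread between samples. A list adjusted p is that of a gene list from camera with an estimated correlation between genes. Early means e8.5, e9.0 and e10.5, and late means e15.0, e17.0, e19.0 and P0.

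The first question was how the mature placenta differs from the early one. The largest rises on this scale belonged to gene families that are expanded in rodents. Ceacam14, a pregnancy-specific glycoprotein relative, rose by 8.29 ± 0.42, to an intensity of 13830 at e19.0. Its intensity at e8.5, 8.29, lay under the added 16, so the size of the rise depended on that constant (9.20 with 1 and 7.10 with 64 added). The cathepsin protease Cts6 rose by 7.92 ± 0.35 and the prolactin-like hormone Prl7a2 by 7.21 ± 0.31, from e8.5 intensities of 20.1 for each, with 10 late and 9 early replicates. In the other direction the embryonic beta-like globin Hbb-bh1 fell by 5.33 ± 0.26 and the cyclin Ccna2 fell by 4.37 ± 0.09. In all, 2081 genes changed, 1062 higher and 1019 lower in the late placenta. For 1572 of them no late replicate overlapped any early one.

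Among the 13 measured pregnancy-specific glycoproteins and related Ceacam genes, 11 rose and 1 fell (list adjusted p = 0.0924). Ceacam12 rose by 7.60 ± 0.30, Psg18 by 7.53 ± 0.22 and Psg16 by 7.29 ± 0.24. The member that fell was Ceacam9, by 4.24 ± 0.18, and Ceacam15 did not pass at 0.43 ± 0.31. Of 10 placental cathepsins, 7 rose and 1 fell (list adjusted p = 0.136). Cts3 rose by 7.68 ± 0.28, Ctsm by 7.04 ± 0.23 and Ctsq by 5.33 ± 0.27, while Ctla2b stayed below the threshold at 0.92 ± 0.25. Of 17 members of the prolactin family, 10 rose and 4 fell (list adjusted p = 0.24). Prl8a8 rose by 7.10 ± 0.26, Prl8a6 by 7.04 ± 0.26, Prl3a1 by 5.83 ± 0.26 and Prl3c1 by 3.08 ± 0.32. Prl4a1 fell by 3.65 ± 0.15, and Prl7c1 did not pass at -0.88 ± 0.23. The list medians were 5.66 for the glycoproteins, 4.43 for the cathepsins and 1.44 for the prolactins.

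Markers of the trophoblast compartments moved in both directions. Of 13 spongiotrophoblast and glycogen cell genes, 6 rose and 3 fell (list adjusted p = 0.213): Tpbpb rose by 4.46 ± 0.16, the VEGF receptor gene Flt1 by 3.67 ± 0.17 and Tpbpa by 2.47 ± 0.14. The imprinted growth regulator Phlda2 fell by 3.87 ± 0.13 and the transcription factor Ascl2 fell by 1.55 ± 0.08. Of 16 labyrinth and syncytiotrophoblast genes, 5 rose and none fell (list adjusted p = 0.116), among them the nuclear receptors Pparg (2.28 ± 0.15) and Rxra (1.13 ± 0.09) and the homeobox gene Esx1 (1.33 ± 0.14). Of 8 giant cell genes, 2 rose and 3 fell, where adrenomedullin (Adm) fell by 1.97 ± 0.19 and Hand1 not past the threshold at -0.53 ± 0.13. Among 18 trophoblast stem and progenitor genes, 1 rose and 5 fell (list adjusted p = 0.266). The pluripotency-related genes Lin28a and Sall4 fell (-3.38 ± 0.17 and -2.40 ± 0.08), as did Eomes (-1.65 ± 0.09) and Elf5 (-1.40 ± 0.07). Cdx2 (-0.37 ± 0.09) and Esrrb (-0.56 ± 0.08) did not pass. With dim genes left out, the median of the stem and progenitor list changed sign.

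The genes of cell division fell almost as a block. Of 35 cell cycle genes, 32 fell and none rose, with a list median of -2.43. Among them were the replication licensing gene Mcm5 (-4.25 ± 0.13), Cdc6 (-4.01 ± 0.11), Birc5 (-3.96 ± 0.12), Top2a (-3.93 ± 0.15), Cdk1 (-3.90 ± 0.08) and Mki67 (-2.66 ± 0.21). Cdk1 intensity was 4846 ± 128 (SD, n = 3) at e8.5, 3831 ± 144 (n = 3) at e12.0, 1387 ± 40.3 (n = 2) at e13.5 and 199 ± 4.77 (n = 2) at e19.0. The 31 oxidative phosphorylation genes had 6 that fell and none that rose (list adjusted p = 0.213), led by Cyc1 (-1.63 ± 0.09). The 26 ribosomal protein genes had 3 that fell (list adjusted p = 0.24), led by Rpl14 (-2.72 ± 0.12). All 3 measured embryonic haemoglobins fell (list adjusted p = 0.155), Hbb-y by 3.25 ± 0.34 and Hba-x fell by 2.28 ± 0.19. Of 18 steroid synthesis genes, 5 fell, 1 rose and 12 were not called (list adjusted p = 0.154). Star, the cholesterol carrier of the mitochondrion, fell by 4.17 ± 0.13, the lipoprotein receptor gene Scarb1 fell by 3.47 ± 0.12 and the side-chain cleavage enzyme gene Cyp11a1 fell by 3.35 ± 0.14. Hsd3b3, another steroid enzyme gene, fell by 3.97 ± 0.13. The cortisone reductase gene Hsd11b1 rose by 2.87 ± 0.23.

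Of 33 nutrient transporters, 16 rose, 3 fell and 14 were not called (list adjusted p = 0.109). The iron exporter gene Slc40a1 rose by 3.09 ± 0.14, the amino acid transporters Slc7a8 by 2.48 ± 0.25 and Slc38a4 by 1.76 ± 0.19, and the calcium-binding protein gene S100g by 2.40 ± 0.24. The glucose transporter gene Slc2a3 fell by 2.45 ± 0.14. Of 31 imprinted genes, 8 rose and 3 fell (list adjusted p = 0.155), with Dlk1 up by 1.70 ± 0.16 and Igf2 short of the threshold at 0.86 ± 0.13. Interferon response genes had 7 of 22 members higher and none lower (list adjusted p = 0.0924), among them Usp18 (2.86 ± 0.13), Oasl2 (2.80 ± 0.13) and Irf7 (2.17 ± 0.09). Of 29 extracellular matrix genes, 10 rose and 1 fell (list adjusted p = 0.116), with Dcn, Timp3 and Bgn up by 2.71 ± 0.23, 2.67 ± 0.20 and 2.34 ± 0.13. Macrophage markers rose in 6 of 20 cases (list adjusted p = 0.222), such as Cd68 (2.16 ± 0.12) and Csf1r (1.85 ± 0.09). Endothelial markers had 3 of 18 higher and 1 lower (list adjusted p = 0.24), with Plvap up by 2.23 ± 0.10 and the apelin receptor gene Aplnr at -1.48 ± 0.14. Smooth muscle markers had 2 of 13 higher (list adjusted p = 0.116), Mylk (1.98 ± 0.10) and Myh11 (1.59 ± 0.07). Complement and coagulation genes had 5 of 26 higher and 1 lower (list adjusted p = 0.155), and 8 of 26 higher with the first e9.0 placental sample left out.

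Markers of tissues next to the placenta also changed. Yolk sac endoderm genes fell in 10 of 21 cases and rose in none (list adjusted p = 0.413). The retinol carrier Rbp4 fell by 3.56 ± 0.31, the apolipoprotein gene Apoc2 fell by 2.94 ± 0.20 and Cubn fell by 2.18 ± 0.20, while Afp did not pass at 0.18 ± 0.57. Without the pair of e8.5 samples taken up in another lysis buffer, 6 of these genes fell and 1 rose, and without e8.5 altogether 5 fell and 1 rose. Uterine natural killer genes fell in 8 of 22 cases (list adjusted p = 0.24), among them the granzyme genes Gzmd (-2.21 ± 0.27) and Gzmg (-1.89 ± 0.25) and the perforin gene Prf1 (-1.32 ± 0.19). The mean of that list was 7.56 at e8.5, 8.47 at e9.0 and 8.33 at e10.5, against 7.18 to 7.81 at the late stages. The late level thus lay below e9.0 and e10.5 but near that of e8.5. Of 28 decidual stromal genes, 4 rose and 6 fell in placenta. The intensity of decidual stromal genes in placental samples was 30.2% of that in decidua of the same stage in the first e9.0 sample, against 13.9% and 5.19% in the other e9.0 samples. It was 3.47% to 3.98% in the 3 samples at e8.5 and 4.84% to 12.5% in the samples of every stage from e10.5 on for which decidua was sampled. Left out, that e9.0 sample took the count of changed genes from 2081 to 2136.

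**Figure D1:**
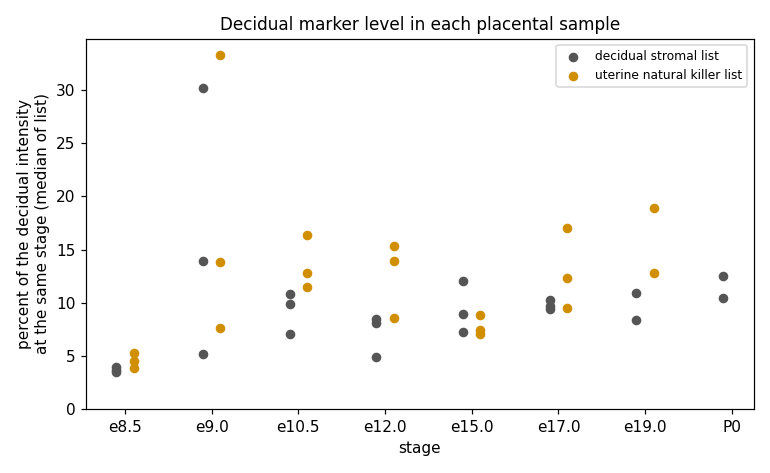
Intensity in each placental sample as a percent of the mean decidual intensity at the same stage (vertical axis), by stage, as the median over decidual stromal genes and over uterine natural killer genes with a decidual intensity over 1000. 1 of 3 samples at e9.0 stands at 30.2% for the stromal genes, and no uterine natural killer gene was bright enough at P0 for a value.

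Tested as lists with camera and a preset correlation of 0.01, cell cycle genes moved down (adjusted p = 5.7e-27), and this held with an estimated correlation (adjusted p = 0.00723). No other list in the late placenta passed with an estimated correlation. The lists given with a list adjusted p above had passed with the preset correlation alone. Short of the threshold with the preset correlation were definitive erythroid genes (2 of 17 up, 1 down), hypoxia genes (5 of 23 up, 3 down) and immediate early and heat shock genes (3 of 21 up, 2 down). The same held for uterine epithelial genes (3 of 20 up, 2 down), neutrophil genes (1 of 19 up, Chil3), giant cell genes and decidual stromal genes. Of 2 probe sets for Hbb-b2, 1 passed upward and the other downward.

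The second question was how decidua changes over the same interval. Ceacam11 rose by 6.54 ± 0.37 (93.0-fold), Prl8a6 by 6.19 ± 0.31 and the retinol carrier Rbp4 by 5.83 ± 0.36, with 8 late and 6 early replicates. The metallothionein gene Mt4 fell by 5.44 ± 0.31 (43.3-fold), the prolactin-like gene Prl3c1 fell by 5.02 ± 0.37 (32.5-fold) and the signalling protein gene Bmp2 fell by 4.49 ± 0.24. In all, 919 genes changed, 545 higher and 374 lower, and for 760 of them no late replicate overlapped any early one.

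Pregnancy-specific glycoprotein genes rose in 11 of 13 cases and fell in 1, with a median of 4.20 (list adjusted p = 0.0188). Ceacam14 rose by 6.54 ± 0.49, Ceacam12 by 6.23 ± 0.35, Psg16 by 6.09 ± 0.27, Ceacam13 by 5.34 ± 0.30 and Psg18 by 5.33 ± 0.25. Spongiotrophoblast and glycogen cell genes rose in 9 of 13 cases with none lower, among them Tpbpb (4.99 ± 0.18), Prl8a8 (4.60 ± 0.30), Prl7b1 (4.38 ± 0.27), Tpbpa (3.52 ± 0.16), Flt1 (3.03 ± 0.20) and the cell cycle inhibitor gene Cdkn1c (2.60 ± 0.18). Of 17 prolactin genes, 10 rose and 3 fell (list adjusted p = 0.142), and of 10 cathepsins, 6 rose and 1 fell (list adjusted p = 0.19). Cts3 rose by 5.37 ± 0.33 and Cts6 by 3.60 ± 0.41, while Cts7 fell by 3.57 ± 0.17. Igf2, the growth factor gene, led the imprinted genes (9 of 31 higher, 1 lower, list adjusted p = 0.0563) with 3.85 ± 0.15, and the neuronal-type protein gene Bex1 rose by 5.74 ± 0.23. For genes at least 4 times brighter in late placenta than in early decidua, the rise in decidua was set against the gap between early decidua and late placenta. With the early decidual intensity thus subtracted from both, late decidua covered a median of 60.1% of the gap for 7 spongiotrophoblast genes and 33.2% for 11 pregnancy-specific glycoproteins. It covered 24.7% for 9 prolactins, 15.3% for 6 labyrinth genes, 9.21% for 6 cathepsins and 2.59% for 10 nutrient transporters, and 11.9% for all 409 such genes. The median was 24.7% for the 55 of these genes over 8000 in late placenta, against 9.02% for 155 dimmer ones and 10.4% for the 199 dimmest. With nothing subtracted, late decidua stood at a median of 62.6% of the late placental intensity for the spongiotrophoblast and 23.2% for the labyrinth genes.

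Immune cell markers changed in both directions. Uterine natural killer genes fell in 11 of 22 cases and rose in none. They included the granzyme genes Gzma (-4.20 ± 0.22), Gzmc (-3.51 ± 0.24) and Gzmb (-3.08 ± 0.22) and the perforin gene Prf1 (-4.06 ± 0.22). Prf1 intensity was 6583 ± 1100 (SD, n = 2) at e10.5, 2446 ± 816 (n = 2) at e15.0 and 124 ± 32.1 (n = 2) at P0. Macrophage markers rose in 11 of 20 cases with none lower: the lysozyme genes Lyz1 and Lyz2 by 3.31 ± 0.36 and 3.16 ± 0.25, the protease gene Ctss by 2.87 ± 0.29, and the complement genes C1qa, C1qb and C1qc by 2.60 ± 0.24, 2.55 ± 0.25 and 2.25 ± 0.19. Lyz2 went from 825 ± 229 (n = 2) at e10.5 to 11740 ± 2067 (n = 2) at e19.0. The macrophage-secreted lectin gene Chil3, the single neutrophil and inflammation gene of 19 that rose, was up by 4.63 ± 0.18.

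Of 18 endothelial markers, 11 fell and 1 rose, with falls of Aplnr (-4.37 ± 0.17), Emcn (-2.71 ± 0.12), Plvap (-2.26 ± 0.11) and Sox17 (-2.12 ± 0.12). Decidual stromal genes fell in 9 of 28 cases and rose in none (list adjusted p = 0.192). They included the tryptophan-degrading enzyme gene Tdo2 (-3.62 ± 0.50), the activin antagonist gene Fst (-3.20 ± 0.17) and Hand2 (-1.42 ± 0.24), whereas the progesterone receptor gene Pgr (-0.36 ± 0.24) and Prl8a2 (-0.24 ± 0.22) did not pass. Other falls were Lipg (-4.84 ± 0.22), Tmsb15a (-4.45 ± 0.21), Bco1 (-4.36 ± 0.24), Hephl1 (-4.35 ± 0.22), Tac2 (-4.31 ± 0.37) and Sprr2h (-4.23 ± 0.25). Of 18 steroid genes, 5 fell and 2 rose (list adjusted p = 0.0558): the progesterone-metabolizing enzyme gene Akr1c18 fell by 3.12 ± 0.25 and the estrogen sulfotransferase gene Sult1e1 rose by 4.33 ± 0.22. Cell cycle genes fell in 8 of 35 cases, Top2a (-2.12 ± 0.18) and Cdk1 (-1.75 ± 0.09) among them.

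Hypoxia response genes rose in 10 of 23 cases, with the oxygen sensor gene Egln3 up by 3.82 ± 0.13, Ankrd37 by 2.31 ± 0.11, P4ha1 by 1.94 ± 0.13 and Adm by 1.72 ± 0.22. Immediate early and heat shock genes rose in 5 of 21 cases, led by Ier3 (2.10 ± 0.14) and Atf3 (1.77 ± 0.08). Of 29 matrix genes, 9 rose and 3 fell (list adjusted p = 0.11), with Lum at 4.89 ± 0.28 and Bgn at -2.93 ± 0.15. Tissue factor (F3) led the 7 of 26 complement and coagulation genes that rose, at 2.94 ± 0.18. The uterine epithelial list had 5 of 20 members higher, and 4 of them were keratins: Krt8 (2.68 ± 0.15), Krt18 (2.68 ± 0.08), Krt19 (2.08 ± 0.19) and Krt7 (1.45 ± 0.16). These keratin genes were also bright in late placenta (6634 to 14730, against 599 to 1894 in early decidua), and their rise covered 15.8% to 71.6% of the gap between early decidua and late placenta. Nutrient transporters had 6 of 33 higher, such as S100g (3.23 ± 0.28). Definitive erythroid genes had 2 of 17 higher, Car2 (1.62 ± 0.19) and Hbb-b2, and no interferon gene of 22 passed. Atf3, S100g, Car2 and Hbb-b2 were also at least 4 times brighter in late placenta than in early decidua. Their rise covered 74.2%, 25.2%, 90.7% and 18.6% of the gap between the 2, in the same order.

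With an estimated correlation, 10 lists held in decidua. The adjusted p was 0.0188 for the pregnancy-specific glycoproteins, 0.00232 for spongiotrophoblast, hypoxia and uterine natural killer genes, 0.00205 for endothelial genes and 0.0256 for cell cycle and uterine epithelial genes. It was 0.024 for macrophage genes and for immediate early genes, and 0.0496 for complement genes. Prolactins (adjusted p = 0.142), cathepsins (0.19), stromal genes (0.192), imprinted genes (0.0563), matrix genes (0.11), steroid genes (0.0558), labyrinth genes (0.142), oxidative phosphorylation genes (0.306) and ribosomal protein genes (0.497) passed with the preset correlation alone. Of 3 probe sets for Rxra, 1 passed in the direction opposite to the brightest.

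**Figure D2:**
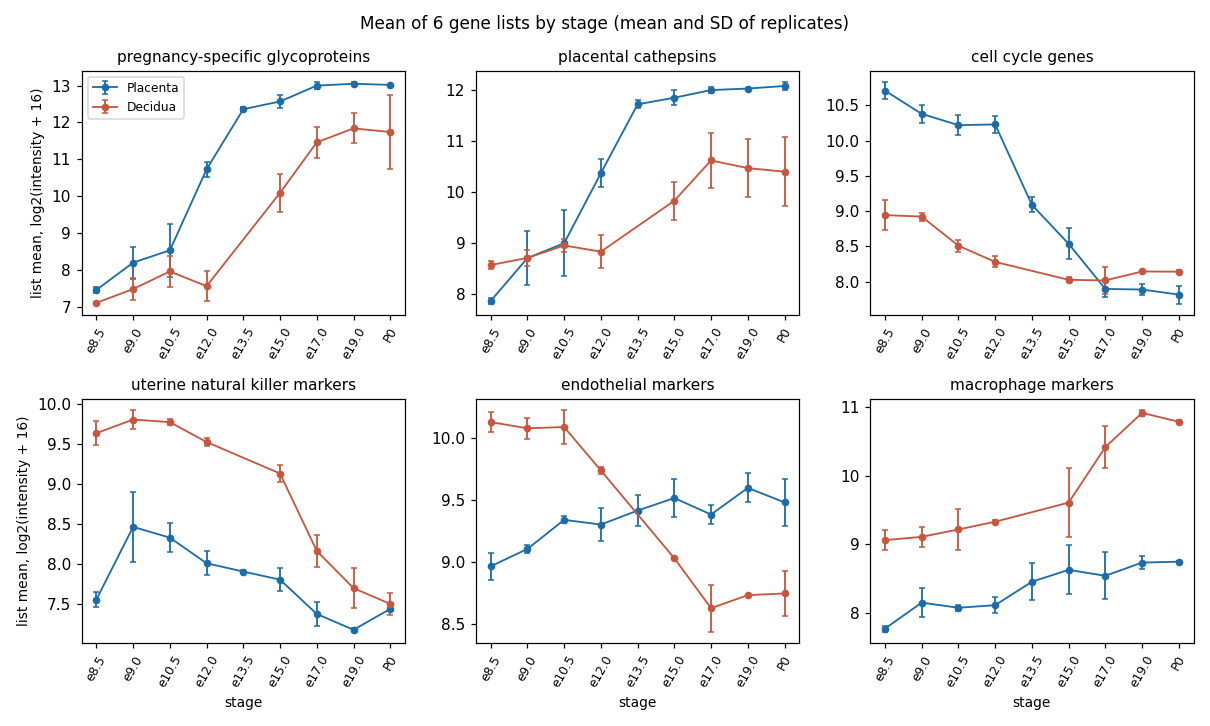
Mean of 6 gene lists by stage in placenta and decidua, in log2(intensity + 16), with points at the mean and bars at the SD of 2 or 3 replicates. Cell cycle genes in placenta went from 10.2 at e12.0 to 7.90 at e17.0, and uterine natural killer genes in decidua from 9.78 at e10.5 to 7.50 at P0.

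The late-minus-early changes of the tissues overlapped. Of the genes higher late in placenta, 210 were also higher late in decidua, where 31.8 would be shared if the lists were independent, and 73 were lower in both against 20.9. Opposite changes were seen for 37 genes that rose in placenta and fell in decidua (21.8 if independent) and for 20 that fell in placenta and rose in decidua (30.5). The counts under independence are over all 18193 genes, dim ones included, which lowers them. Placental transcripts in late decidua, whose source stays open, could add to the genes higher in both.

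The third question was whether the change with gestation differed between placenta and decidua, tested as the placental late-minus-early difference minus the decidual one. The prolactin-like gene Prl3c1 had the largest positive value, 8.10 ± 0.49. It rose in placenta and fell in decidua, from 7217 ± 483 (SD, n = 2) at e8.5 in decidua to 57.4 ± 6.91 (n = 2) at e19.0. Rbp4 went the other way with -9.38 ± 0.47, falling in placenta and rising in decidua from 92.7 ± 12.3 (n = 2) at e9.0 to 12100 ± 865 (n = 2) at e19.0. The matrix proteoglycan gene Bgn had 5.27 ± 0.20, the lipase gene Lipg 5.18 ± 0.29, Tent5a 5.08 ± 0.29 and the leptin receptor gene Lepr 4.82 ± 0.20. On the negative side were Bex1 (-5.16 ± 0.30), Egln3 (-4.97 ± 0.17), the endothelin gene Edn2 (-4.91 ± 0.22) and Prl7c1 (-4.70 ± 0.35). In all, 2273 genes differed, 1070 toward placenta and 1203 toward decidua.

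Endothelial markers differed in 12 of 18 cases, every one toward placenta, with Plvap at 4.48 ± 0.15, Emcn at 3.71 ± 0.16 and Clec14a at 3.52 ± 0.16. Cell cycle genes differed in 30 of 35 cases, every one toward decidua, with Mcm5 at -3.26 ± 0.21 and Cdc6 at -3.19 ± 0.17. These were the lists that held with an estimated correlation, at adjusted p = 0.0065 and 0.01. Interferon genes (9 of 22 higher, adjusted p = 0.122 with an estimated correlation), uterine natural killer genes (9 of 22 higher, 0.183) and cathepsins (6 of 10 higher, 0.228) did not hold. The same was true of hypoxia genes (7 of 23 lower, 0.122), yolk sac genes (11 of 21 lower and 1 higher, 0.43) and uterine epithelial genes (6 of 20 lower and 2 higher, 0.228). Imprinted genes split into 6 higher and 7 lower, with Mest at 2.62 ± 0.20 and Igf2 at -2.98 ± 0.20. Adjusted over the list alone, 13 of 28 decidual stromal genes passed against 12 over all genes, and in every other list and main comparison both counts were equal.

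**Figure D3:**
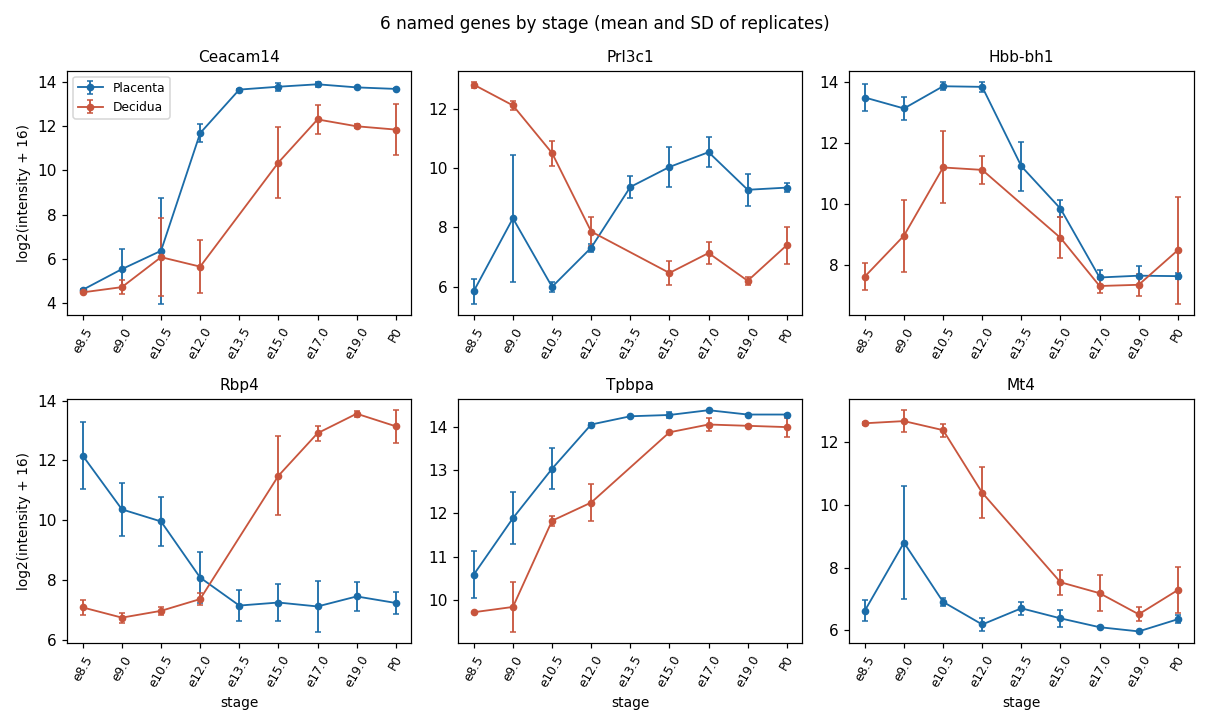
Log2(intensity + 16) of 6 named genes by stage in placenta and decidua, with points at the mean and bars at the SD of 2 or 3 replicates. Prl3c1 and Rbp4 changed in opposite directions in the tissues, and Prl3c1 and Mt4 at e9.0 in placenta had a wide spread.

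The fourth question was which genes separate placenta from decidua over the 8 stages sampled in both. The carbonic anhydrase gene Car4 was higher in placenta by 4.50 ± 0.10 (22.7-fold), with 6956 ± 263 (SD, n = 3) at e15.0 against 169 ± 31.3 (n = 2) in decidua. The fatty acid binding protein gene Fabp3 was higher by 4.34 ± 0.11, the connexin gene Gjb2 by 4.32 ± 0.13, the steroid-inactivating enzyme gene Hsd17b2 by 4.15 ± 0.10 and the imprinted gene Dlk1 by 3.96 ± 0.12. Also higher were Dcaf12l1 (3.94 ± 0.10), Vnn1 (3.86 ± 0.12), the protease gene Prss8 (3.80 ± 0.09), Afp (3.80 ± 0.41) and the transcription factor gene Hand1 (3.19 ± 0.09). Lower in placenta were Shisa3 (-5.39 ± 0.13), the water channel gene Aqp1 (-5.38 ± 0.16), the creatine synthesis gene Gatm (-5.14 ± 0.23), Ampd3 (-5.03 ± 0.18), the protease inhibitor gene Tfpi2 (-4.86 ± 0.19), Coch (-4.73 ± 0.14), Tdo2 (-4.70 ± 0.30), Tnfrsf11b (-4.67 ± 0.24), Medag (-4.67 ± 0.20) and Spon1 (-4.63 ± 0.14). In all, 1993 genes differed, 991 higher and 1002 lower in placenta, and 1783 of them kept 1 direction at each of the 8 stages.

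Decidual stromal genes were lower in placenta in 19 of 28 cases and higher in 2. The difference was -4.23 ± 0.14 for Hoxa10, -3.91 ± 0.15 for Pgr and -3.80 ± 0.15 for Hand2. Macrophage genes were lower in 11 of 20 cases, uterine natural killer genes in 9 of 22, matrix genes in 11 of 29, complement genes in 10 of 26 and interferon genes in 5 of 22, with none higher in any of the last 5 lists. The list adjusted p was 0.0684 for the stromal, natural killer, matrix and complement lists, 0.0743 for macrophage and 0.0703 for interferon genes. Higher in placenta were 19 of 35 cell cycle genes, with Rrm1 and Rrm2 lower at -1.75 ± 0.06 and -2.50 ± 0.10. Also higher were 11 of 13 pregnancy-specific glycoproteins, 13 of 31 imprinted genes (4 lower), 9 of 17 prolactins (Prl8a2 lower at -2.01 ± 0.14), 6 of 10 cathepsins (2 lower) and all 3 embryonic haemoglobins. The uterine epithelial list had 9 of 20 genes higher in placenta and 2 lower, with a median of 0.75. It therefore does not mark uterine epithelium alone in these samples. Phlda2 was higher by 3.61 ± 0.09, Esx1 by 3.58 ± 0.10 and Zfp42, a stem cell gene, by 2.77 ± 0.09. No list passed with an estimated correlation. The lowest adjusted p was then 0.0684, for lists that included stromal, cell cycle, matrix, uterine natural killer and imprinted genes, and it was 0.172 for the pregnancy-specific glycoproteins. For prolactins it was 0.344 and for embryonic haemoglobins 0.247. Over the 4 main comparisons, 76 of 116 list tests passed with the preset correlation, 13 with an estimated one and 98 with fry. The fry test asks whether the genes of a list move 1 way on balance and does not compare them with other genes. In placenta late against early, the stromal list had a negative median (-0.25) and mean (-0.07) and a test direction upward. Median and mean had opposite signs for definitive erythroid (-0.13 and 0.11), uterine epithelial (-0.16 and 0.05) and neutrophil genes (-0.08 and 0.02). The same was true between tissues for giant cell (-0.10 and 0.43), smooth muscle (0.13 and -0.11), endothelial (0.03 and -0.06) and steroid genes (-0.03 and 0.11). In the difference between tissues it was true for steroid (0.05 and -0.40) and Y-linked genes (0.12 and -0.09).

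Decidua is maternal, so Y-linked transcripts served as a measure of fetal tissue in it. The measure depends on the share of male fetuses in each pooled sample, which the labels do not give. Of 3 measured Y-linked genes, the translation factor gene Eif2s3y was higher in placenta by 2.14 ± 0.18, and Uty (0.22 ± 0.08) and Kdm5d (0.11 ± 0.05) did not pass by their brightest probe sets. Another of the 4 probe sets of Uty passed, at 1.16 higher in placenta. The mean of the list was 0.82 higher in placenta. All 3 were dim. Eif2s3y in decidua had a mean intensity of 26.7 over the late stages and 17.1 over the early ones, against 171 in late placenta. Its late-minus-early difference in decidua did not pass in limma (0.36 ± 0.30, adjusted p = 0.413). That standard error is pooled over all groups, and placental samples ranged from 4.89 to 8.80 on the log2 scale. Within decidua the SD was 0.22 late and 0.10 early, and an exact permutation of its replicates gave p = 0.005 (two-sided). Among late samples the highest value in both tissues was in the first e19.0 sample (8.80 in placenta, 5.71 in decidua). The lowest was in the second P0 sample (4.89 and 4.99). At e17.0 the first 2 samples differed little, in opposite order (6.95 and 7.05 in placenta, 5.41 and 5.37 in decidua). Whether decidual values follow placental ones of the same number was not tested.

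Between neighbouring stages of the placenta, 218 genes passed from e12.0 to e13.5 (63 higher, 155 lower), close to 201 from e9.0 to e10.5 and 199 from e10.5 to e12.0. The order of these steps was not fixed: with array weights the counts were 223, 482 and 439, and by adjusted p alone 740, 1036 and 653. Cts6 rose by 5.63 ± 0.69, Prl8a8 by 5.34 ± 0.51, Ceacam12 by 3.99 ± 0.60, Psg16 by 3.71 ± 0.46 and Prl8a6 by 3.65 ± 0.52. Falls were largest for the erythroid gene Hemgn (-3.67 ± 0.37), Ceacam9 (-2.89 ± 0.36), the erythrocyte anion exchanger gene Slc4a1 (-2.62 ± 0.50), Hbb-bh1 (-2.61 ± 0.52) and Mtm1 (-2.37 ± 0.28). Slc4a1 and Hbb-bh1 no longer passed without the second e13.5 sample (adjusted p = 0.0816 and 0.128). Of 35 cell cycle genes, 25 fell at this step. From e10.5 to e12.0, 9 of 13 pregnancy-specific glycoproteins rose and 5 of 18 steroid genes fell, and 199 genes passed (150 higher, 49 lower). From e8.5 to e9.0, 142 genes passed (88 higher, 54 lower), including 12 of 21 yolk sac genes lower, and 11 of 28 decidual stromal and 7 of 22 uterine natural killer genes higher. Without the first e9.0 placental sample these became 13, 5 and 5, and 106 genes passed. Without the pair of e8.5 samples in the other lysis buffer, 9 genes passed.

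The later placental steps had fewer called genes in the main setting, though some earlier steps fell below 101 genes under other settings. From e15.0 to e17.0, 101 genes passed, with all 3 embryonic haemoglobins and 8 cell cycle genes lower. From e13.5 to e15.0, 7 passed (1 to 18 with 1 sample left out), and from e17.0 to e19.0, 18 (5 to 43). From e19.0 to P0 limma called 0 genes, with 410 at an unadjusted p under 0.05. That is fewer than the 0.05 share of 18193 genes expected by chance alone. From e9.0 to e10.5, 201 genes passed (98 higher, 103 lower), and without the first e9.0 sample 109 passed (82 higher, 27 lower). The direction at that step moved with the scaling: 153 were higher and 62 lower after quantile normalization, and 161 and 55 after scaling to the 75th percentile. The median of all genes at that step was -0.06 as deposited, 0.04 after quantile normalization and 0.06 after the other scaling. From e10.5 to e12.0 the split became 118 and 67, and 115 and 69, in the same order. Single samples weighed on these counts. The step from e9.0 to e10.5 ranged from 96 without the first e10.5 sample to 506 without the third e9.0 sample. The step from e10.5 to e12.0 ranged from 84 without the second to 593 without the third e10.5 sample.

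In decidua 221 genes passed from e12.0 to e15.0 (151 higher, 70 lower), the longest step, since decidua was not sampled at e13.5. Ceacam12 rose by 4.89 ± 0.66, Ceacam14 by 4.71 ± 0.90, Ceacam11 by 4.47 ± 0.68, Prl8a6 by 4.46 ± 0.57 and Psg16 by 4.43 ± 0.51. The largest falls were those of Sprr2h (-3.45 ± 0.45), Prl7a1 (-3.39 ± 0.32), Akr1c18 (-3.19 ± 0.47), Tmsb15a (-3.09 ± 0.40) and Mt4 (-2.86 ± 0.57). Ceacam14 failed without the first e12.0 or the first e15.0 sample (highest adjusted p = 0.0951), and Mt4 without the second e12.0 sample (adjusted p = 0.153). The count was 129 without the second e15.0 sample and 146 without the second e12.0 sample. At this step 9 of 13 pregnancy-specific glycoproteins and 7 of 13 spongiotrophoblast genes rose and 6 of 18 endothelial genes fell. From e15.0 to e17.0, 7 of 22 uterine natural killer genes fell and 6 of 20 macrophage genes rose among 67 changed genes (34 higher, 33 lower). That split was 49 and 22 after quantile normalization and 51 and 28 after 75th percentile scaling, and 15 genes passed without the first e17.0 sample. From e9.0 to e10.5, 84 genes passed, with 6 of 17 prolactins higher, but only 38 to 58 with any 1 sample left out. From e10.5 to e12.0, 136 passed (72 higher, 64 lower, or 52 and 83 after quantile normalization), and from e17.0 to e19.0, 42 (24 higher, 18 lower, or 21 and 25). With 1 sample left out these ranged from 49 to 141 and from 9 to 56. From e8.5 to e9.0 limma called 0 genes, with 598 at an unadjusted p under 0.05, fewer than the 0.05 share of 18193 genes expected by chance. From e19.0 to P0 it called 1, the lectin gene Clec4n (-1.04 ± 0.17), which failed without either of 2 samples, the first at e19.0 and the first at P0 (highest adjusted p = 0.352). Without the second P0 sample 42 genes passed at that last step.

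**Figure D4:**
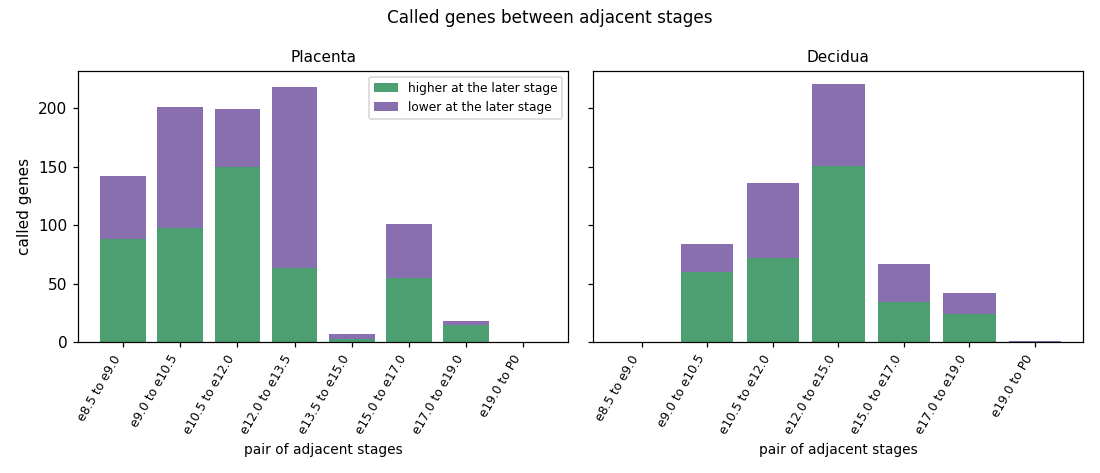
Number of genes past the threshold between neighbouring stages in placenta and decidua, split into genes higher and lower at the later stage. The tallest bars stand at e12.0 to e13.5 in placenta (218) and at e12.0 to e15.0 in decidua (221). Steps differ in length of time, and the latter is the longest because decidua was not sampled at e13.5.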

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

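The tests of placental transcripts in late decidua, of the first e9.0 placental sample, of natural killer genes in placenta and of other splits of the samples were chosen after the results were seen. A difference between the tissues in their late-minus-early change, tested in the limma model, marked the following results. Placenta minus decidua, the log2 value was 8.10 for Prl3c1, 5.27 for Bgn, 5.18 for Lipg, 5.08 for Tent5a and 4.82 for Lepr. It was -9.38 for Rbp4, -5.16 for Bex1, -4.97 for Egln3, -4.91 for Edn2 and -4.70 for Prl7c1. The list medians were 1.72 for endothelial markers and -1.69 for cell cycle genes. No group held 4 or more replicates, so no group was searched for an extreme sample.

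In late decidua 9 of 13 spongiotrophoblast genes and 11 of 13 pregnancy-specific glycoproteins rose (camera adjusted p with an estimated correlation 0.00232 and 0.0188). Placental tissue of every zone carried over in dissection would bring all its abundant transcripts. Of 55 genes over 8000 in late placenta, 15 stood on these lists, and their median in late decidua was 16% to 72.7% of placenta of the same stage over 8 replicates. Of the other 40, 20 stayed below that median in all 8, 5 below 0.5 times it (Cts6, Ctsr, Fabp3, Gjb2 and Lepr) and 3 below 0.25 times it. Chosen on the first replicate of each late stage, 7 genes lay below 0.5 times it, and 5 of these also did so in the second. This argues against such tissue as the whole cause. Tissue of the spongiotrophoblast zone alone stays open. A comparison of the lists does not decide: the rise over early decidua, as a percent of late placenta minus early decidua, was 44.7 points higher for 7 spongiotrophoblast than for 6 labyrinth genes (exact permutation p = 0.0117, two-sided). With nothing subtracted it was 39.4 points (exact permutation p = 0.0186, two-sided). The subtracted percent was higher for the brightest genes, with a median of 24.7% for the 55 genes over 8000 against 11.9% for all 409. Less the median of genes of like brightness, the gap between the lists was 30.8 points (exact permutation p = 0.135, two-sided). These permutations exchanged genes between the lists. Genes are not independent replicates, so the p-values of the list comparison do not measure the spread between samples. Cells of the fetus within late decidua stay open as a source of the rise in these lists. Embryonic haemoglobin transcripts were present in decidua at e15.0, with a list mean of 11.57 against 12.29 in placenta and 7.673 in e8.5 decidua. By e17.0 the mean was 8.204 in decidua and 9.543 in placenta. Because it fell in both tissues, this mean cannot follow fetal cells over the late stages. Nor can it tell which cells carried the spongiotrophoblast and glycoprotein transcripts. The 2 Y-linked probe sets called between tissues were higher in late than in early decidua, by 0.36 for Eif2s3y and 0.24 for Uty (mean 0.30, exact permutation p = 0.00333, two-sided). Both lay near the floor. Limma's adjusted p for Eif2s3y was 0.413, with a standard error pooled over all groups, the more variable placental samples included. By brightest probe set Uty was lower by 0.27 and Kdm5d by 0.14, and the mean of the 3 genes changed by -0.02 (exact permutation p = 0.780, two-sided). These probe sets of Uty and Kdm5d were not called between tissues, so fetal cells would move them little. The mean of the 3 genes therefore cannot count against fetal cells. Maternal expression of the same genes stays open, since Eif2s3y lay near the floor in decidua. Its rise was 6.25% of late placenta minus early decidua and its late intensity 15.6% of that in late placenta, and the sources cannot be told apart for these genes.

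The 3 e9.0 placental samples differed from each other, and the explanations were tested for the first. Of 493 genes over 4 times higher in decidua at e8.5 and e10.5, 95.7% were higher in the first sample than in the mean of the others. Decidual tissue in that sample is thus a candidate explanation. The third sample deviated about as far the other way, with 4.67% of these genes higher, and the second stood between at 28.6%. Across genes the deviation had r = 0.479, -0.169 and -0.434 with decidua minus placenta, in order of replicate. A difference in developmental stage found no support for the first sample. Its deviation had r = -0.0383 across genes with the change from e8.5 to e10.5 (genes are not independent replicates). No biological explanation other than stage was tested.

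Of 22 uterine natural killer genes, 8 fell in late placenta and none rose, and the list did not pass with an estimated correlation (camera adjusted p = 0.24). In 9 early placental samples these genes stood at 1.30 times (median; 0.995 to 1.63) the share of the decidual level that stromal genes had, so decidual tissue in placental samples may account for their presence. Natural killer cells resident in the placenta stay open: the lowest ratio was 0.995, and a share held by such cells cannot be told apart from a mixed one at these values.

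Other splits of the samples were compared with the real counts of changed genes. Of 100 splits each, the real one gave the highest count in every main comparison. For placenta late against early it was 2081 (highest other 1123) and for decidua late against early 919 (highest other 559). Placenta against decidua gave 1993 (highest other 640) and the difference between tissues 2273 (highest other 1695). In each of these, 1 of 100 splits reached the real count, and the median of the other splits was 0. Splits that mix stages or tissues put real differences into the spread within groups, which lowers their counts. The comparison therefore cannot decide whether chance could give the real counts. For steps of 3 against 3 samples the 10 splits are too few for a share under 0.05. The real and highest other counts were 142 and 64 for placenta from e8.5 to e9.0, 199 and 0 from e10.5 to e12.0, and 101 and 24 from e15.0 to e17.0, each with 1 split as large. From e9.0 to e10.5 they were 201 and 368, with 2 splits as large, and the larger one grouped the first 2 e9.0 samples with the third e10.5 sample.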

How the results depend on the processing

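The first e9.0 placental sample left out, the e8.5 replicates merged, list counts under other settings, the percents with nothing or with genes of like brightness subtracted, the level of bright genes and the Y-linked probe sets called between tissues were chosen after seeing the data, and all other alternatives before. No called value named in the text changed direction in a fit with 1 value per gene, but some were no longer called. Of up to 597 named values, called or not, 30 lost their call with the mean of probe sets, 6 with array weights, 5 with quantile normalization, 5 with 75th percentile scaling and 2 with the replicate block. A pseudocount of 64 lost 13. Fewer samples lost 9 without e8.5, 4 without P0, 4 without the other lysis buffer and 2 with the e8.5 merger. The first technical array, a fit on the own tissue, a pseudocount of 1 and the linear trend lost 1 each. With replicates left out 1 at a time, 18 lost it at least once. With each probe set on its own, 19 of 182 called values of genes with more than 1 probe set had a probe set of the other sign, and 2 had one called the other way, both for Hbb-b2 (-1.48 to 3.25 in placenta). Prf1, Cts7, Top2a, Dcn and Myh11 were among the 19. The 4 main counts stayed within 1.5 times under every alternative except the linear trend over stages. The trend gave 3261 for placenta late against early, 1623 for decidua and 3640 for the difference between tissues. It used more stages and measured the fitted change from the first to the last stage, a wider span than late minus early. With the same log2 threshold, its counts are thus not of the same measure. Steps were less stable. Quantile normalization gave 13 for placenta e13.5 to e15.0 and 1 for decidua e8.5 to e9.0. A pseudocount of 64 gave 1 for decidua e8.5 to e9.0, 0 for decidua e19.0 to P0 and 0.53 for the Y-linked mean. With dim genes left out, placenta e17.0 to e19.0 gave 8, decidua e10.5 to e12.0 gave 89, e17.0 to e19.0 gave 27 and e19.0 to P0 gave 0. The mean of probe sets gave 126 for placenta e10.5 to e12.0 and 0 for decidua e19.0 to P0. Array weights gave 482 for placenta e9.0 to e10.5, 439 for e10.5 to e12.0, 39 for e17.0 to e19.0, 4 for decidua e8.5 to e9.0 and 0 for e19.0 to P0. A fit on the own tissue gave 11 for placenta e13.5 to e15.0 and, in decidua, 45 for e9.0 to e10.5, 146 for e12.0 to e15.0, 33 for e15.0 to e17.0, 4 for e17.0 to e19.0 and 0 for e19.0 to P0. Every array with a random block gave 11 for placenta e13.5 to e15.0. For placenta e8.5 to e9.0, leaving out the other lysis buffer gave 9 with fewer samples, and the e8.5 merger gave 68. Without the first e9.0 sample, placenta e9.0 to e10.5 gave 109. Estimated correlation left 13 of 76 list calls. Alone, Eif2s3y differed between tissues by 2.14, Kdm5d by 0.11 and Uty by 0.22, against 0.82 for their mean. Where no reason is given, the cause was not tested. The limma counts of 0 for decidua e19.0 to P0 stand beside 312 genes at an unadjusted p under 0.05 in the main setting. Those 312 are fewer than the 0.05 share of 18193 genes expected by chance. The signal of dim genes over background limits what low values can show.

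With the replicate number as a block shared by placenta and decidua, the counts were 2081, 900, 1990 and 2262 for the 4 main comparisons and the Y-linked mean was 0.83, and no count of a step moved by over 1.5 times. The labels do not say that a number marks a litter. Of 16 pairs with the same number, 13 had a correlation of deviations over 0.1 (-0.22 to 0.57), and 14 placental and 12 decidual samples correlated best with their own number. At e19.0 and P0, with 2 samples in each tissue, both pairs of a stage necessarily give the same value (0.41 and 0.24). The 16 pairs are thus not independent, and no value expected by chance was computed.

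With each replicate left out in turn, placenta late against early ranged from 2056 to 2136, decidua from 899 to 965, tissues from 1959 to 2016, their difference from 2229 to 2382 and the Y-linked mean from 0.76 to 0.89. The placental steps ranged, in order of stage, from 75 to 239, 96 to 506, 84 to 593, 159 to 267, 1 to 18, 69 to 140, 5 to 43 and 0 to 18. The decidual steps ranged from 0 to 3, 38 to 58, 49 to 141, 129 to 262, 15 to 83, 9 to 56 and 1 to 42. Omissions that moved a count by over 1.5 times follow, named by stage and replicate. Placenta e8.5 to e9.0 gave 75 without e8.5 replicate 1, 86 without e8.5 replicate 2 and 239 without e9.0 replicate 3. Placenta e9.0 to e10.5 gave 109, 123 and 506 without e9.0 replicates 1, 2 and 3, and 96 and 491 without e10.5 replicates 1 and 3. Placenta e10.5 to e12.0 gave 101, 84 and 593 without e10.5 replicates 1, 2 and 3, and 102 without e12.0 replicate 1. Placenta e13.5 to e15.0 gave 18 and 1 without e13.5 replicates 1 and 2, and 4 and 18 without e15.0 replicates 1 and 2. Placenta e17.0 to e19.0 gave 43 and 11 without e17.0 replicates 1 and 3, and 5 without e19.0 replicate 1. Placenta e19.0 to P0 gave 18 without P0 replicate 1 and 1 without e19.0 replicate 2. Decidua e8.5 to e9.0 gave 3 and 1 without e8.5 replicates 1 and 2. Decidua e9.0 to e10.5 gave 38 and 40 without e9.0 replicates 1 and 2, and 47 without e10.5 replicate 1. Decidua e10.5 to e12.0 gave 83 without e10.5 replicate 2 and 49 without e12.0 replicate 1. Decidua e12.0 to e15.0 gave 146 without e12.0 replicate 2 and 129 without e15.0 replicate 2. Decidua e15.0 to e17.0 gave 37 without e15.0 replicate 2 and 15 without e17.0 replicate 1. Decidua e17.0 to e19.0 gave 12 without e17.0 replicate 2 and 9 without e19.0 replicate 1. Decidua e19.0 to P0 gave 4 without e19.0 replicate 2, and 7 and 42 without P0 replicates 1 and 2.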

Other observations

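The distance measured here between arrays was not part of the planned comparisons. At e8.5 the root mean square log2 difference between the first technical arrays of placental replicates 1 and 2 was 0.202, against 0.341 between the technical arrays of replicate 1 and 0.174 between those of replicate 2. In decidua the same values were 0.184, 0.345 and 0.150. The second array of replicate 1 differed from every other e8.5 array of its tissue by at least 0.249 in placenta and 0.345 in decidua. Whether the replicate numbers of these arrays are right is not settled, and the averages of technical arrays follow the labels. With replicates 1 and 2 of e8.5 counted as 1 sample in each tissue, 68 genes passed in placenta from e8.5 to e9.0 against 142, and with the first technical arrays alone 193 did.

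Genes of the labyrinth list differed widely in their late decidual intensity as a plain percent of late placental intensity. The lactate transporter gene Slc16a3 stood at 61.2% and Fzd5 at 54.5%, against 4.53% for Esx1 and 17.1% for Pparg. Among spongiotrophoblast genes Pcdh12 stood at 146% (1123 in late decidua, 768 in late placenta), Tpbpa at 80.4%, Tpbpb at 62.8% and Prl8a8 at 25.3%.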
